A study of Mus musculus with 6 samples.

How the data were processed

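RNA was measured by poly(A)-selected RNA-seq in 6 libraries of preSC cells, a mouse cell line described in the labels as a precursor line of small cell lung cancer (SCLC). The cells of each library carried a lentiviral pLKO.1 vector. The 3 control libraries comprised 2 with the empty vector (shEmpty, control replicates 1 and 2) and 1 with a non-silencing hairpin (shNS, control replicate 3). The 3 knockdown libraries (shCrebbp replicates 1, 2 and 5) each carried a different short hairpin RNA against Crebbp, numbered 1, 2 and 5. The labels do not say whether the libraries came from separate cultures or days, so p-values measure the spread between these libraries, and within the knockdown group that spread includes differences between hairpins.

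Per the labels' protocols, messenger RNA was taken from 500 ng of total RNA with oligo(dT) beads and libraries were made with an Illumina-compatible NEBNext Ultra kit, with index primers added during PCR. The submitters' processing notes name bcl2fastq 1.8.2, TopHat2 2.0.12, HTSeq 0.6.1 and the mouse build mm9. The annotation, the strand setting and the rule for overlapping genes are not given in the sources used here. The deposited files hold raw read counts per gene symbol, 1 file per library, which the authors had not normalized or pooled. No molecular identifiers are named, so counting errors assume that reads are independent. The reference annotation at hand is of another build (GRCm38), so it was used for names, transcript length and GC content, and no coordinates are given. Of the 23284 gene names in the files, 22821 (98.0%) matched a transcript of that annotation. Genes with near-identical copies, and genes that overlap others, are uncertain, since reads aligned to several places were set aside and reads of overlapping genes cannot be apportioned.

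The 5 HTSeq summary rows of each file were left out of library sizes and tests. They held between 24.8% and 28.9% of all counts, mostly reads outside annotated genes (14.8% to 18.1%) and reads aligned to several places (9.00% to 9.74%). The remaining gene counts totalled 19805000, 16447000 and 13688000 in control replicates 1, 2 and 3, and 13622000, 13937000 and 14651000 in shCrebbp replicates 1, 2 and 5, so that a normalized value (CPM) of 1 stood for 13.6 to 19.8 reads. Between 16038 and 16568 genes had at least 1 read in a library. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom over genes between 4.08 and 28.4), and each was kept as a separate sample.

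Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood test with robust estimation), with intercept and group as the only terms, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 (the primary analysis). The filter left 13390 genes. CPM values are TMM-normalized, log2 CPM uses a prior count of 2, errors of CPM are SDs over 3 libraries, and the standard error (SE) of a log2 fold change was taken from the fold change and its F statistic. Gene lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, which asks whether the genes of a list move on balance in one direction. The 20 pathway lists and 9 lists of cell type markers were fixed before the data were examined, as were the design and most alternatives. Lists with fewer than 5 tested members were not tested as lists. The shNS library was compared with the 2 shEmpty libraries in a fit with 3 groups that pools the spread over all 6 libraries, on the assumption that the single shNS library varies like the others. For each hairpin library the log2 ratio to the mean of the 3 controls was computed without a test. Correlations of these ratios were set beside those of 100 simulated sets of unchanged libraries. In each set all 6 libraries were drawn from the control means, with genes independent and the same gene-wise dispersion in both groups.

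Genes were named by a rule fixed in advance. It names Crebbp, Ep300, Rb1, Trp53, Mycl and Cdh1, and up to 10 genes in each direction with the largest change among those past the threshold, with an average log2 CPM of at least 2 and all 3 shCrebbp libraries on the same side of all 3 controls, leaving out provisional gene names and pseudogenes. It also names up to 4 called members of each pathway list by smallest p, or the 2 with the smallest p where none was called, and the 2 most abundant tested members of each marker list. Not every gene that the rule names is discussed here, and genes named outside the rule are said to be so. Gene symbols are those of the files, so Mycl appears as Mycl1.

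The alternatives were DESeq2 1.42.0, limma-voom with and without library quality weights, RLE and upper quartile normalization, no filter and a filter of 1 CPM in 3 libraries, non-robust estimation, a 2-fold minimum, and leaving out each library. Thinning to equal depth and a correction for GC content and transcript length were added after seeing the data, as were DESeq2 and limma-voom with each library left out, and the simulated correlation for shNS. The scripts were tested on simulated counts for the comparison of shCrebbp with control (13390 genes, 5 sets with 200 changed genes). edgeR recovered 36.7% of genes changed 1.5-fold, 72.5% of those changed 2-fold and 92.1% of those changed 4-fold, and 8.34% of its calls were unchanged genes; for DESeq2 that share was 20.2%. With no gene changed, edgeR called a mean of 0.4 genes per set. The paired analysis was left out, since the numbers of the knockdown group are hairpin numbers. Figures were drawn with matplotlib 3.10.9.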

Results

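The transcriptome of preSC cells was profiled to identify genes regulated by Crebbp, which encodes the histone acetyltransferase CREB-binding protein. Cells carrying 3 different Crebbp hairpins (hairpins 1, 2 and 5, 1 library each) were compared with cells carrying control vectors (2 shEmpty libraries and 1 shNS library). Reads counted in genes ranged from 13622000 to 19805000 per library. On principal components of log2 CPM, the first component (42.0% of variance) placed the 3 controls between -28.2 and -13.0 and the hairpin libraries at 24.2, 32.6 and 5.17 for hairpins 1, 2 and 5. The second component (31.6%) separated hairpin 1 (37.5) from hairpin 2 (-29.4). Log2 CPM correlated at 0.990 to 0.995 between control libraries and at 0.969 to 0.980 between hairpin libraries, across genes. Between a hairpin and a control library it correlated at 0.965 to 0.985, so hairpin libraries were no closer to each other than to controls. Hairpin 5 correlated at 0.984 to 0.985 with the controls, and at 0.978 and 0.980 with hairpins 1 and 2.

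Crebbp transcripts were lower in each hairpin library than in each control. The targeted gene stood at 66.2, 69.6 and 69.4 CPM in control replicates 1, 2 and 3 and at 46.2, 58.3 and 48.9 CPM with hairpins 1, 2 and 5. The group means were 68.4 ± 1.91 CPM in controls and 51.1 ± 6.35 CPM with the hairpins (SD, n = 3 each), a 1.34-fold difference with a log2 fold change of -0.42 ± 0.10 (SE). This difference did not pass the threshold over all genes (edgeR adjusted p = 0.0999). It passed with DESeq2 (adjusted p = 0.0163), with limma-voom using library quality weights (adjusted p = 0.0153), and in edgeR without hairpin 2 (log2 fold change -0.53, adjusted p = 0.0478). Its paralogue Ep300, which encodes p300, stood at 115 ± 5.24 CPM in controls and 117 ± 11.1 CPM with hairpins (adjusted p = 0.936). No member of the list of 19 histone acetyltransferases and no member of the 18 histone deacetylases passed the threshold in the primary edgeR analysis, and camera gave adjusted p = 0.559 and 0.638. In edgeR with 1 library left out, Crebbp passed without hairpin 2 and 1 deacetylase was called lower without hairpin 1. DESeq2 called 1 acetyltransferase lower, and 1 deacetylase higher and 1 lower. Adjusted over the list alone, 0 acetyltransferases passed, and 1 deacetylase was higher and 1 lower. In the latter list Hdac9 had a log2 fold change of 0.49 ± 0.11 (adjusted p = 0.0858) and Hdac11 of -0.88 ± 0.23 (adjusted p = 0.116). The acetyltransferase gene next in rank to Crebbp was Myst4, at 0.23 ± 0.09 (adjusted p = 0.240).

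**Figure D1:**
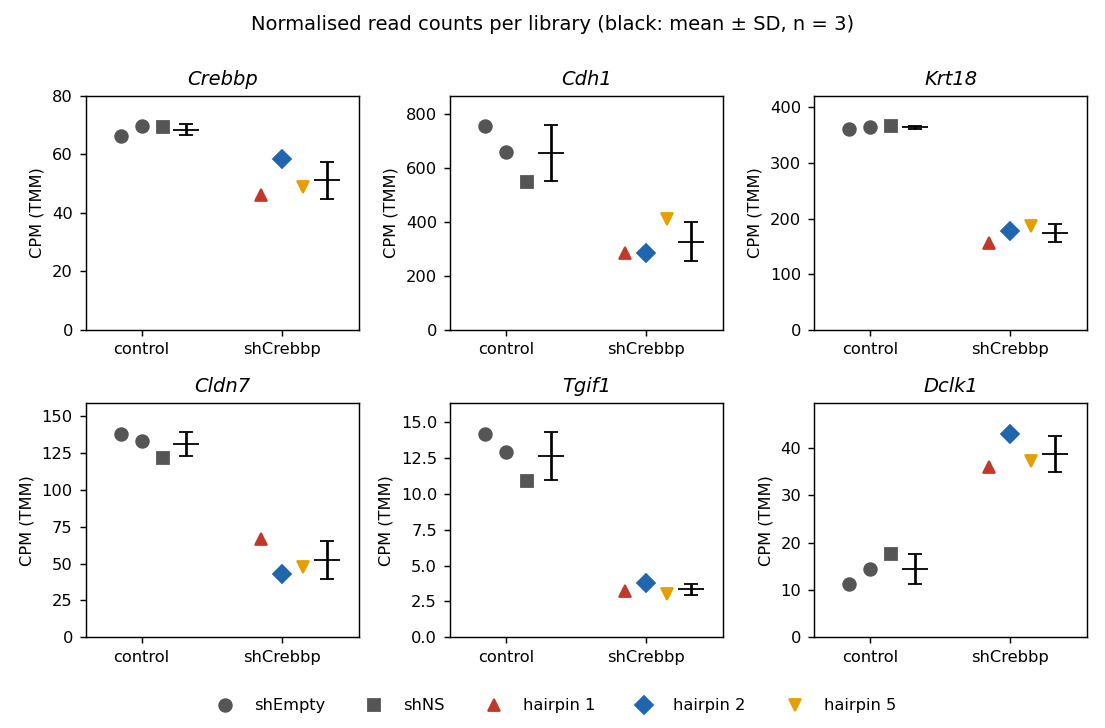
TMM-normalised CPM (vertical axes, linear from 0) of 6 genes in each of the 6 libraries, with shEmpty as circles, shNS as squares and the 3 Crebbp hairpins as coloured symbols; black bars give the mean ± SD (n = 3). Crebbp had means of 68.4 and 51.1 CPM, a difference that did not pass the adjusted threshold, while Cdh1, Krt18, Cldn7 and Tgif1 lay lower and Dclk1 higher in each hairpin library than in each control.

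Pooling the hairpins, 168 of 13390 tested genes passed an adjusted p of 0.05 in edgeR, and 131 of these (78.0%) were lower with the hairpins. The lower genes had a median log2 fold change of -1.0 and the 37 higher genes one of 1.08. At least a 2-fold change was seen in 66 of the lower and 21 of the higher genes. All 168 had the 3 hairpin libraries on one side of the 3 controls. Over all tested genes that separation was seen in 3003 (22.4%), 1530 above and 1473 below, against the 10% that chance gives for 3 libraries against 3. Genes vary together, so the share in a given grouping of libraries can lie far from 10%. The excess was not tested, and other groupings were not counted.

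Tmprss4, a transmembrane serine protease, fell 4.20-fold (log2 fold change -2.07 ± 0.17), from 28.6 ± 2.37 to 6.80 ± 1.38 CPM. Muc1, a membrane mucin, fell 3.34-fold, from 22.4 ± 3.03 to 6.70 ± 0.656 CPM. Anxa1, which encodes the phospholipid-binding protein annexin A1, fell 3.24-fold, from 52.0 ± 5.84 to 16.1 ± 4.25 CPM. Tgif1, a transcriptional corepressor of TGF-beta signalling, fell 3.80-fold, from 12.7 ± 1.68 to 3.33 ± 0.400 CPM. Ifitm3, an interferon-induced antiviral membrane protein, fell 3.92-fold, to 3.59 ± 0.524 CPM. Eppk1, which encodes the cytolinker epiplakin, fell 3.81-fold, and Ahnak fell 3.87-fold. The remaining members of this set were Ccdc64b (3.84-fold), Rab26 (3.47-fold) and the growth factor gene Fgf5 (3.26-fold). Adjusted p values of these 10 genes lay between 0.00593 and 0.0277 (edgeR).

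The higher genes of largest change, among those called with an average log2 CPM of at least 2, included Wif1, a secreted Wnt inhibitor. Wif1 rose 3.78-fold from 15 ± 4.11 to 56.3 ± 27.8 CPM. Gabra5, a GABA-A receptor subunit, rose 3.32-fold from 14.1 ± 0.0968 to 46.9 ± 20.2 CPM. Dclk1, a doublecortin-like kinase, rose 2.69-fold from 14.4 ± 3.14 to 38.7 ± 3.79 CPM. Nkx6-1, a homeobox transcription factor, rose 2.69-fold from 3.62 ± 0.524 to 9.73 ± 2.07 CPM. Itpkb, an inositol trisphosphate kinase, rose 4.25-fold and Swap70 rose 3.79-fold. Hdgfrp3 (3.22-fold), Zfyve9 (3.07-fold), Lipa, which encodes lysosomal acid lipase (3.06-fold), and the small GTPase gene Rab6b (3.01-fold) completed the set. Adjusted p values lay between 0.0118 and 0.0497 (edgeR).

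The count of called genes depended on the control libraries. Without either shEmpty library edgeR called 0 genes, although 1332 genes (without control replicate 1) and 1238 genes (without control replicate 2) had an unadjusted p under 0.05, and DESeq2 then called 252 and 220 genes while limma-voom called 0 in both. Without shNS edgeR called 48 genes, and without hairpins 1, 2 and 5 it called 368, 101 and 389. The direction of the 168 genes was kept in all 168 under each of these 6 omissions. This was all but fixed in advance, because the hairpin libraries of all 168 lay wholly above or wholly below the controls. It is therefore no check of stability. DESeq2 over all libraries called 730 genes, 59.3% of them lower.

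Epithelial genes were lower across the hairpin libraries. Of the 24 tested genes of the epithelial identity list, 10 were called lower and none higher, and all 24 had a negative log2 fold change (median -0.86). Krt18 and Krt8 (the latter named outside the rule), which encode the keratin pair of simple epithelia, fell 2.10-fold (from 364 ± 2.20 to 174 ± 15.7 CPM) and 2.22-fold (from 874 ± 60.1 to 393 ± 78.9 CPM). Spint1, a membrane protease inhibitor, fell 2.22-fold from 111 ± 4.96 to 50.1 ± 6.05 CPM, and St14, the matriptase gene, fell 2.23-fold from 119 ± 5.77 to 53.1 ± 6.56 CPM. Ehf, an epithelial ETS transcription factor, fell 2.93-fold from 34.4 ± 0.360 to 11.7 ± 2.20 CPM. When adjusted over the list alone, 18 of the 24 were lower. Epcam, the epithelial cell adhesion molecule gene (also outside the rule), had a log2 fold change of -0.87 ± 0.21 and did not pass over all genes (edgeR adjusted p = 0.0971). Camera ranked the list below other genes (adjusted p = 2.01e-36), but not with an inter-gene correlation estimated at 0.37 (adjusted p = 0.142 with an estimated correlation). Fry gave an adjusted p of 0.0280.

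Most tight junction genes followed the same direction. Of 26 tested members 8 were called lower and none higher over all genes. Fold changes were negative in 21 and positive in 5, with a median log2 fold change of -0.51. Adjusted over the list alone, 14 were lower and 1 was higher. F11r, which encodes junctional adhesion molecule A, fell 1.87-fold from 127 ± 1.8 to 67.8 ± 8.40 CPM. Crb3, an apical polarity protein gene, fell 2.27-fold from 17.1 ± 1.48 to 7.52 ± 0.439 CPM. The claudin genes Cldn7 and Cldn3 fell 2.50-fold (131 ± 8.30 to 52.5 ± 12.7 CPM) and 2.09-fold (112 ± 12.7 to 53.7 ± 8.67 CPM). The scaffold gene Tjp1 (outside the rule) had a log2 fold change of -0.05 and did not pass (adjusted p = 0.93). Camera ranked the list below other genes (adjusted p = 1.62e-15; adjusted p = 0.142 with an estimated correlation), and fry gave an adjusted p of 0.0280.

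Cdh1, the E-cadherin gene, fell from 653 ± 103 to 326 ± 73.6 CPM (log2 fold change -1.0 ± 0.17, edgeR adjusted p = 0.0361). It stood at 753, 657 and 548 CPM in control replicates 1, 2 and 3 and at 282, 285 and 411 CPM with hairpins 1, 2 and 5. In the list of 20 tested adherens junction and desmosome genes, Cdh1 and the periplakin gene Ppl (1.52-fold) were called lower and the nectin gene Pvrl3 higher (log2 fold change 0.59, 30.8 ± 0.505 to 46.3 ± 1.6 CPM). Adjusted over the list alone, 9 members were lower and 2 higher. Camera gave an adjusted p of 5.89e-05 for the list, and adjusted p = 0.213 with an estimated correlation. Fry gave an adjusted p of 0.0645. Over the union of the 3 epithelial and junction lists, 20 of 70 tested members (28.6%) were called lower against 0.833% of the other tested genes (two-sided Fisher's exact test, p = 1.54e-24, treating genes as independent). The count of 20 became 0 without control replicate 1 or 2, 9 without shNS, and 25, 14 and 24 without hairpins 1, 2 and 5. In 40 of the 70 members the hairpin libraries all lay below the controls and in 4 all above.

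**Figure D2:**
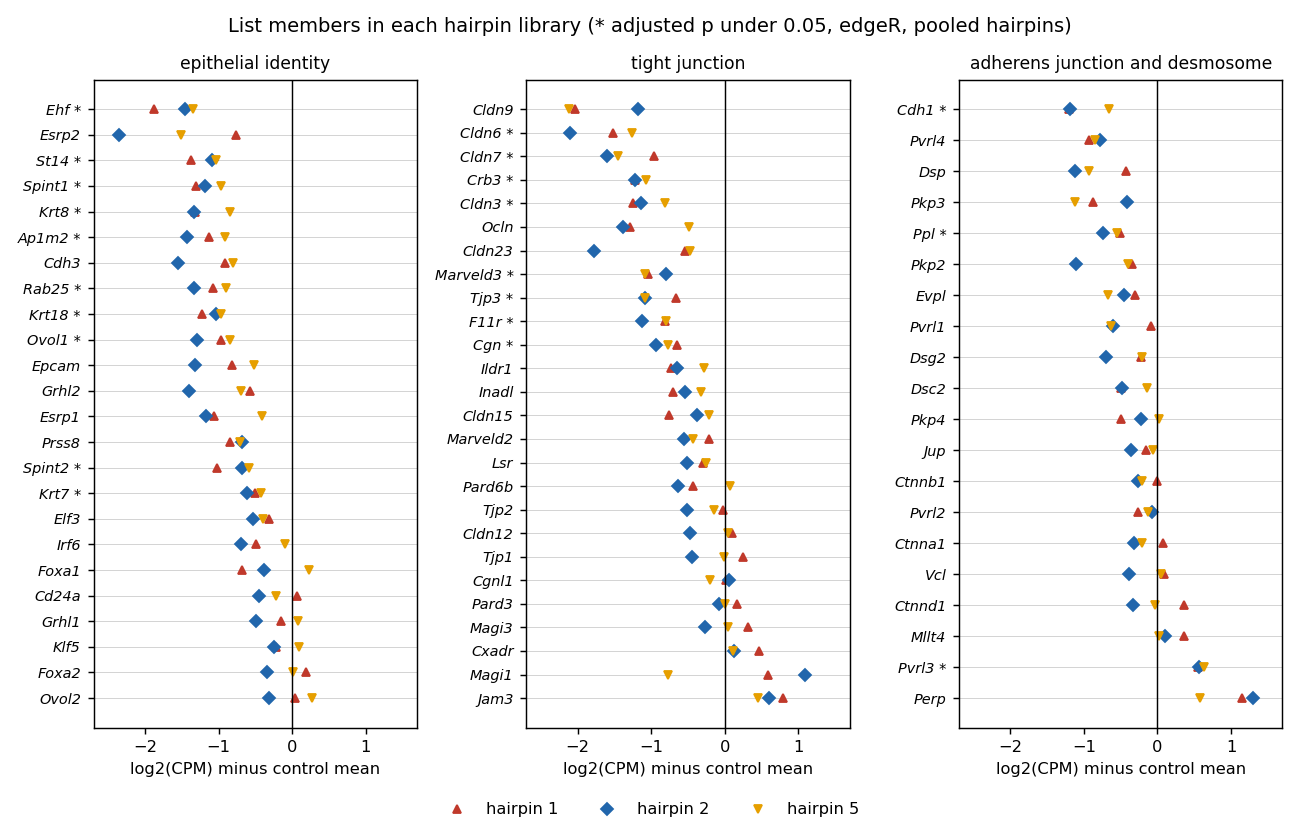
Log2 CPM minus the mean of the 3 controls (horizontal axes) for each tested member of the 3 epithelial and junction lists, with 1 symbol per hairpin library; asterisks mark members with an edgeR adjusted p under 0.05 for the pooled hairpins. The symbols of most members lie below 0, and Pvrl3 is the 1 member called higher.

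Mesenchymal genes did not pass the threshold in the primary edgeR analysis. None of 13 tested members was called over all genes there, while 1 was called higher by DESeq2 and by edgeR without hairpin 1 or without hairpin 5. Camera gave an adjusted p of 0.0930 with a median log2 fold change of 0.36, and 0.0124 without hairpin 5. Fn1, which encodes fibronectin, stood at 14.5 ± 1.5 CPM in controls and 37.2 ± 16.0 CPM with hairpins (adjusted p = 0.0784), and Zeb1, a transcriptional repressor of epithelial genes, at 59.4 ± 5.33 and 77.4 ± 13.1 CPM (adjusted p = 0.203). The list had 1 higher member adjusted over the list alone.

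Neuroendocrine genes as a list were not called with all 6 libraries, and single members lay at the threshold. None of 38 tested members passed over all genes in the primary edgeR analysis. With all 6 libraries edgeR called 0 or 1 lower under the other settings (1 with upper quartile normalization, without a filter, with the 1 CPM filter, without robust estimation, at equal depth and with the GC correction), while DESeq2 called 2 lower and 1 higher, limma-voom 2 lower, and limma-voom with quality weights 2 lower and 2 higher. In edgeR 3 were called lower without hairpin 5, and 1 lower and 1 higher without hairpin 1. The mean log2 ratio to controls over the list was -0.28 with hairpin 1 and 0.04 with hairpins 2 and 5. Of the 38, 18 had positive and 20 negative fold changes, and adjusted over the list alone 2 were lower. The closest to the threshold were Ret, a receptor tyrosine kinase gene (290 ± 31.6 to 167 ± 33.5 CPM, adjusted p = 0.0505), and Calca, the calcitonin and CGRP gene (1803 ± 209 to 875 ± 267 CPM, log2 fold change -1.04 ± 0.20, adjusted p = 0.0558). Camera gave an adjusted p of 0.187, and 0.0309 without hairpin 5. Mycl1 stood at 73.7 ± 19.7 CPM in controls and 48.8 ± 19.6 CPM with hairpins (adjusted p = 0.381). The tumour suppressor genes Rb1 and Trp53 had reads in each library, at 192 ± 22.6 and 28.8 ± 2.95 CPM in controls and 169 ± 37.7 and 26.1 ± 2.78 CPM with hairpins (adjusted p = 0.622 and 0.644). Counts per gene do not show whether either gene is intact in these cells.

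In the Notch list 2 of 24 tested members were called lower, both ligand genes. Dll4 fell 2.87-fold from 5.04 ± 0.362 to 1.75 ± 0.428 CPM and Dll1 fell 1.52-fold from 43.8 ± 2.25 to 28.9 ± 3.03 CPM (adjusted p = 0.0353 and 0.0377). Adjusted over the list alone, 7 were lower and 1 higher. The mean over members was -0.05, -0.43 and -0.34 with hairpins 1, 2 and 5, against 0.09, 0.001 and -0.10 in control replicates 1, 2 and 3. Hairpin 1 thus lay within the control range. Camera gave an adjusted p of 0.000570, and adjusted p = 0.331 with an estimated correlation. Fry gave an adjusted p of 0.130.

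Interferon-response genes were lower in 33 of 36 tested members by sign, with a median log2 fold change of -0.30. Of these 2 passed, Mx1, an antiviral GTPase gene near the detection limit (1.54 ± 0.138 to 0.284 ± 0.124 CPM), and Parp14 (2.06-fold, 20.1 ± 2.03 to 9.77 ± 1.78 CPM). In all 5 were lower adjusted over the list alone. In the list of MHC and antigen presentation genes, the immunoproteasome subunit gene Psmb8 fell by 0.63 on the log2 scale, from 82.3 ± 4.16 to 53.2 ± 7.38 CPM, as the 1 of 20 members called over all genes; adjusted over the list alone 9 were lower and 1 higher. Camera ranked both lists below other genes (adjusted p = 1.69e-07 and 1.99e-06; adjusted p = 0.213 for both with an estimated correlation). Fry gave adjusted p of 0.0645 for the interferon list and 0.0615 for the MHC list.

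Cell cycle genes differed in sign by phase, and no single gene passed in edgeR with all 6 libraries. DESeq2 called 7 G2 and M phase genes lower and 4 S phase genes higher, limma-voom with quality weights 3 and 7, edgeR without hairpin 5 called 9 and 0, and edgeR without hairpin 1 called 0 and 1. All 29 members of the G2 and M phase list had negative fold changes (median log2 fold change -0.37), with Prc1 at -0.54 ± 0.13 (adjusted p = 0.0918) and Plk1 at -0.48 ± 0.13 (adjusted p = 0.111). The mean over members was -0.41, -0.75 and -0.07 with hairpins 1, 2 and 5, against 0.10, 0.00 and -0.11 in the controls, so that hairpin 5 lay within the control range. Camera gave an adjusted p of 6.69e-12, the estimated correlation was 0.88 and adjusted p = 0.413 with it, and fry gave an adjusted p of 0.202. Of 33 S phase and E2F targets 31 had positive fold changes (median log2 fold change 0.15). Ccne1, the cyclin E1 gene, stood at 0.59 ± 0.13 (adjusted p = 0.0812) and Pcna at 0.30 ± 0.07 (adjusted p = 0.0902). Camera gave an adjusted p of 3.25e-06, adjusted p = 0.213 with an estimated correlation, and fry 0.0461. There were 6 lower G2 and M phase genes and 2 higher S phase genes adjusted over the list alone.

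**Figure D3:**
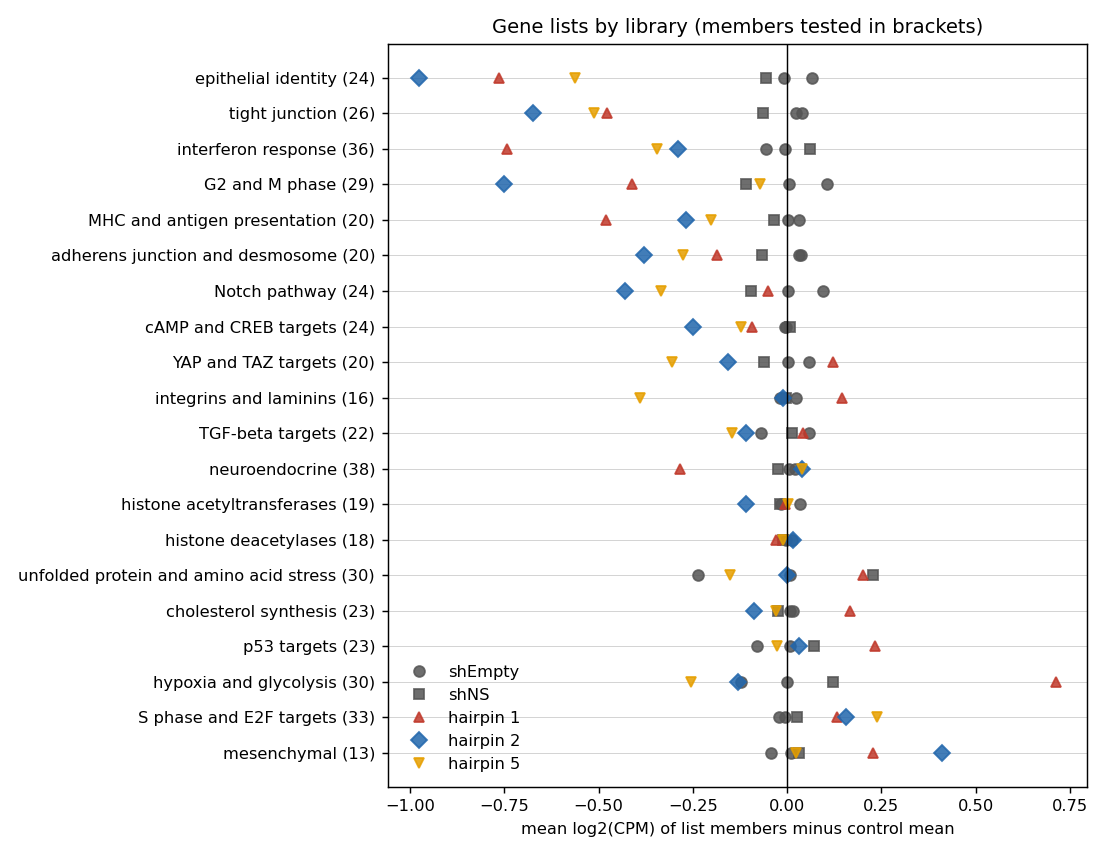
Mean over list members of log2 CPM minus the mean of the 3 controls (horizontal axis) for the 20 pathway lists (vertical axis, members tested in brackets), with 1 symbol per library. The hairpin libraries lie between -0.98 and -0.56 for epithelial identity, and hairpin 1 alone lies at 0.71 for hypoxia and glycolysis.

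The remaining lists were not called by camera with all 6 libraries. With 1 library left out, hypoxia and glycolysis was ranked lower without hairpin 1 (adjusted p = 0.00150) and higher without hairpin 2 or 5 (0.0448 and 0.0124). Ranked lower were also cAMP and CREB targets and the unfolded protein and amino acid stress list, without control replicate 1 (0.0493 and 0.00781) or hairpin 1 (0.0136 and 0.0206), and the integrin and laminin list and YAP and TAZ targets without hairpin 1 (0.0223 for both). Among 22 TGF-beta targets (adjusted p = 0.245, ranked lower although the median log2 fold change was 0.04) Tgif1 fell and Tgfb3, a TGF-beta ligand gene, fell by 0.85 on the log2 scale, from 36.7 ± 3.52 to 20.4 ± 0.494 CPM, and among 20 YAP and TAZ targets (adjusted p = 0.203) the kinase gene Nuak2 fell 2.18-fold from 35.7 ± 3.43 to 16.4 ± 1.83 CPM. In cholesterol synthesis (23 genes, adjusted p = 0.328) Cyp51, the lanosterol demethylase gene, rose by 0.58 on the log2 scale, from 55.3 ± 1.35 to 82.8 ± 6.65 CPM. Adjusted over the list alone, 3 TGF-beta targets were lower and 1 higher, 2 YAP and TAZ targets lower and 1 higher, and 2 cholesterol synthesis genes higher and 1 lower. No member of the other 5 lists passed in the primary edgeR analysis. With all 6 libraries edgeR called 1 cAMP and CREB target lower with upper quartile normalization, 2 without a filter and 1 with the GC correction, and 1 integrin or laminin lower with upper quartile normalization and 1 without a filter. DESeq2 called 4 cAMP and CREB targets, 2 integrins and laminins, 2 p53 targets and 2 unfolded protein and amino acid stress genes lower, 1 p53 target higher, and 0 hypoxia and glycolysis genes. For 24 cAMP and CREB targets (camera adjusted p = 0.0612; 5 members lower adjusted over the list alone), Per1 had a log2 fold change of -0.64 ± 0.13 and Junb of -0.57 ± 0.12 (adjusted p = 0.0591 and 0.0622). For 16 integrins and laminins (camera adjusted p = 0.324; 1 lower over the list alone) Itga3 had a log2 fold change of -0.57 ± 0.12 (adjusted p = 0.0623). For 23 p53 targets (camera adjusted p = 0.372; 2 higher and 2 lower over the list alone) the log2 fold changes were 0.57 ± 0.13 for Ccng1 and -0.48 ± 0.11 for Btg2 (adjusted p = 0.0824 and 0.0946). For the unfolded protein and amino acid stress list of 30 genes (camera adjusted p = 0.245; 0 over the list alone) they were -0.36 ± 0.09 for Hsp90b1 and -0.25 ± 0.07 for Pdia6 (adjusted p = 0.104 and 0.131). In hypoxia and glycolysis (30 genes, camera adjusted p = 0.336; 0 over the list alone) Hk1 had -0.17 ± 0.07 (adjusted p = 0.285), and Hk2 varied between hairpins (log2 ratio to controls 3.36, 1.51 and -1.34 for hairpins 1, 2 and 5, adjusted p = 0.30).

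Markers of other cell types were measured as a description of the cultures. Among the most abundant tested markers were Vwf for endothelium (423 ± 16.3 CPM in controls, 321 ± 137 with hairpins, adjusted p = 0.562), Dcn for fibroblasts (39.1 ± 3.98 and 35.0 ± 25.3 CPM, adjusted p = 0.915), Abca3 for alveolar type 2 cells (75.2 ± 2.72 and 69.7 ± 1.01 CPM, adjusted p = 0.532), Emp2 for alveolar type 1 cells (101 ± 4.72 and 76.0 ± 13.7 CPM, adjusted p = 0.171), Aldh1a1 for club cells (127 ± 7.93 and 96.9 ± 9.20 CPM, adjusted p = 0.0974) and Sox2 for basal cells (106 ± 5.96 and 70.6 ± 26.7 CPM, adjusted p = 0.261). Next in abundance among alveolar markers were Lpcat1 and Etv5 at 23.6 and 17.6 CPM (type 2) and Rtkn2 and Akap5 at 21.9 and 12.2 CPM (type 1) in controls. Many members of these lists were near 0 in controls (here CPM of library totals, without TMM). These included Cdh5 (0.0203), Kdr (0.101) and Cldn5 (0) for endothelium, Col1a1 (0.236), Col3a1 (0) and Lum (0) for fibroblasts, and Trp63 (0), Krt5 (0.0244) and Krt14 (0.0203) for basal cells. They also included Sftpd (0), Slc34a2 (0), Sftpb (0.0985) and Sftpa1 (0.338) for alveolar type 2 cells, with Sftpc at 1.94, Cav1 (0), Clic5 (0.164) and Pdpn (0.530) for alveolar type 1 cells, and Scgb1a1 (0) for club cells. The abundance of single markers does not show any of these cell types to be present. The 1 tested leukocyte marker, Cd68, stood at 4.05 ± 1.30 and 3.93 ± 0.399 CPM (adjusted p = 0.973). The ciliated marker Ccdc40 stood at 30.3 ± 3.08 and 26.6 ± 2.26 CPM (adjusted p = 0.479). By library totals, Ccdc39 stood at 3.50 and 8.19 CPM and Rsph1 at 15.9 and 8.52 CPM. Adjusted over the ciliated list alone, 1 member was higher and 1 lower. Of the tuft cell markers Dclk1 rose, while Avil stood at 13.0 ± 0.770 and 7.86 ± 1.96 CPM (adjusted p = 0.115). Other tuft cell markers were near 0 in controls by library totals, among them Pou2f3 (0.0203), Trpm5 (0.0412), Gfi1b (0.0244) and Chat (0.0817). The less abundant second markers were Pdgfra, Pecam1, Lpcat1, Rtkn2, Tppp3 and Ngfr, with adjusted p between 0.676 and 0.796. The alveolar type 1 and ciliated lists, which had 6 tested members each, were not called by camera (adjusted p = 0.656 for both).

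The control vectors were compared as the background of the experiment. No gene was called between shNS and shEmpty by edgeR, where 100 of 13390 genes had an unadjusted p under 0.05, or by DESeq2. These 100 are fewer than a threshold of 0.05 gives without any difference. With a single shNS library and a spread pooled over the hairpin libraries, the edgeR fit was conservative. The absence of calls does not show that the vectors are alike. Across genes, the log2 difference of shNS from shEmpty correlated at 0.24 with that of the hairpins from all controls, against a mean of -0.02 (-0.05 to 0.02) in 100 simulated sets of unchanged libraries. The simulation drew genes independently, whereas real genes vary together. Its range therefore does not bound what unchanged libraries could give. The 3 controls lay along a gradient, at -28.2, -20.8 and -13.0 on the first component for control replicates 1, 2 and 3, so the 2 shEmpty libraries also differed in that direction, and the correlation was not shown to be specific to shNS.

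Agreement between hairpins was examined across genes, which are not independent replicates. The log2 ratios to the shared controls correlated at 0.37 for hairpins 1 and 2, 0.43 for hairpins 1 and 5 and 0.50 for hairpins 2 and 5. Simulated sets, in which controls and hairpin libraries were all drawn unchanged from the control means, gave a mean of 0.25 and no more than 0.28 for any pair. The simulation drew genes independently with the same gene-wise dispersion in both groups, so it lacks the gradient among the real controls. Real controls also correlated more closely (0.990 to 0.995) than hairpin libraries (0.969 to 0.980). A dispersion common to both groups may therefore overstate the spread of controls. The excess over the simulation is of uncertain size and cannot be read as agreement between hairpins alone. The covariances were 0.0995, 0.0827 and 0.0973 against 0.0255 on average in the simulation, a mean difference of 0.0677 in log2 units squared. With 3 controls no split of the controls was made, and part of the correlation comes from their shared use. The 3 hairpins had 1 library each, so differences between hairpins carry no replicate check.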

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

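The 168 calls of edgeR kept their direction in each alternative that tested them. In all of these alternatives the direction was all but fixed in advance, since the hairpin and control libraries of these genes did not overlap in the primary analysis. RLE and upper quartile normalization, a filter of 1 CPM, limma-voom, non-robust estimation, equal depth and the GC content and length correction (the last 2 chosen after seeing the data) gave 159 to 183 calls. Without a filter 235 genes were called (57 higher, 178 lower). DESeq2 called 730 genes (297 higher, 433 lower) and limma-voom with library quality weights 694 (280 higher, 414 lower); both included all 168, and 59.3% and 59.7% of their calls were lower against 78.0%. With a 2-fold minimum 87 remained (21 higher, 66 lower). Leaving out 1 library gave 0 to 389 calls (0 to 142 higher, 0 to 247 lower): 0 without control replicate 1 or 2, 48 without shNS, and 368, 101 and 389 without hairpins 1, 2 and 5. The smallest edgeR adjusted p was then 0.0513 without control replicate 1 and 0.0678 without control replicate 2. The cause of this loss was not tested. The median log2 fold change of the 20 called epithelial and junction genes was -1.05 and -1.08 there, against -1.07. These genes were picked as lower with all 6 libraries, so their median could hardly move and shows nothing about stability. Those 20 became 34 with DESeq2, 33 with quality weights and 0 to 25 with 1 library left out. Crebbp passed with DESeq2 (-0.42) and with quality weights (-0.46), and ranged from -0.53 to -0.35 with 1 library left out. Camera called 8 lists, 0 with an estimated correlation, 3 with fry, and 8 to 13 with 1 library left out; without hairpin 1 it called 13. The comparison of shNS with shEmpty, with a single shNS library and a conservative edgeR fit, stayed at 0 calls wherever it was run. The mean correlation between hairpins ranged from 0.41 to 0.49 without 1 control. Under RLE and the 1 CPM filter 3001 and 2921 genes separated the groups.

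Of the 79 named genes other than Crebbp, 39 were called and none of these changed sign. For the 39 this was all but fixed in advance in each setting, since their hairpin and control libraries did not overlap in the primary analysis. The 12 changes of sign were in uncalled genes: with quality weights Hk2 (-0.012) and Dcn (0.059), with limma-voom Cd68 (0.050), and with 1 library left out Ep300 (range -0.041 to 0.092), Dcn (-0.87 to 0.26), Pdgfra (-0.13 to 0.67), Cd68 (-0.29 to 0.12), Rtkn2 (-0.34 to 0.0027) and Tppp3 (-0.31 to 0.68). No paired analysis was possible because the numbers of the knockdown libraries name hairpins, not shared cultures. At 1 CPM, about 13.6 to 19.8 reads, genes such as Mx1 rest on few reads.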

Other observations

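The tests of a non-silencing response and of single-hairpin effects, the equal-depth fit and the GC correction were chosen after the main result was seen; the tests of other splits, of dilution, GC content and depth had their outcomes stated before they were run.

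Outside the fixed lists and the naming rule, several called genes stood out, and they are named here after their values were seen. Nts, which encodes the neuropeptide neurotensin, rose from 0.256 ± 0.0451 to 3.89 ± 0.745 CPM, and Fst, the follistatin gene, from 0.668 ± 0.0602 to 5.27 ± 2.51 CPM (SD, n = 3; edgeR adjusted p = 0.00593 and 0.0221). Tro, which encodes trophinin, rose 2.12-fold from 34.1 ± 2.41 to 72.1 ± 5.09 CPM. Among lower genes, Clca1 and Clca4 of the calcium-activated chloride channel regulator family fell 3.16-fold and 2.66-fold (23.7 to 7.49 and 221 to 82.9 CPM); the family has similar copies, so the split of reads between members is uncertain. Tmprss2, another transmembrane serine protease gene, fell 4.41-fold to 0.816 ± 0.418 CPM, and Wfdc2 fell 2.39-fold from 239 ± 10.9 CPM in controls.

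Single libraries stood apart in some lists. Hypoxia and glycolysis genes had a mean log2 ratio to controls of 0.71 with hairpin 1, -0.13 with hairpin 2 and -0.26 with hairpin 5. The unfolded protein and amino acid stress list spread from -0.24 to 0.23 among the 3 controls alone. Histone genes by name (Hist followed by a number) held 0.0405% and 0.0408% of gene counts with hairpins 1 and 2, and 0.0602% with hairpin 5, against 0.0581% to 0.0610% in controls. The libraries were poly(A)-selected, so histone transcripts without a poly(A) tail are largely missed by these shares.

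The first pattern weighed is the number of called genes. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as 168 genes, 37 higher or 131 lower; the highest of the others was 0 in each case, and with 10 splits a share under 0.05 cannot be reached. For gene lists, 5 of the 10 splits called at least the 8 lists of the real one and another split called 12, so camera with its preset correlation calls as many lists from groupings that mix the vectors. A correction for GC content and transcript length left the median absolute log2 fold change of the called genes at 0.972 of its value (95% bootstrap interval over genes 0.964 to 1.01, with values for 166 of 168 genes). This argues against GC content and length as the whole cause. Equal depth left the median at 0.993 (0.982 to 1.02). Thinning lowers the counts of all genes of a library alike, so this ratio could hardly move and does not test depth. At equal depth 167 genes were called, 159 of them among the 168, so most calls did not rest on unequal depth.

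The second pattern is the fall of epithelial and junction genes. Dilution by cells of another type would lower neuroendocrine genes alike, but 34 neuroendocrine genes of at least 10 CPM had a median log2 fold change of -0.10 (bootstrap interval over genes -0.21 to 0.04). The 20 called epithelial and junction genes had -1.07, but they were picked as lower in these same data. Over all 70 tested members of those lists, called or not, the median was -0.51. By library the whole neuroendocrine list had means of -0.28, 0.04 and 0.04 with hairpins 1, 2 and 5, so a part of the fall with hairpin 1 is not covered by this comparison. An off-target of a single hairpin as the whole cause is argued against by leaving out each hairpin: without hairpins 1, 2 and 5, edgeR still called 25, 14 and 24 of the 70 tested members of the 3 epithelial and junction lists lower. A response to expressing any hairpin could contribute and stays open, because only 1 shNS library was made. Over 9 epithelial and junction genes called lower against shEmpty alone, shNS lay 0.0984 of the way to the hairpin libraries. The interval over genes (-0.038 to 0.24) does not cover the spread between libraries. Over all 48 genes called against shEmpty alone the position was 0.19. Over whole lists, shNS had mean log2 ratios to controls of -0.057 (epithelial identity), -0.065 (tight junction) and -0.067 (adherens junction and desmosome). The hairpin means were -0.77, -0.56 and -0.28. The difference of shNS from shEmpty correlated with that of the hairpins at 0.24, although the 2 shEmpty libraries also differed along that axis (first component -28.2 and -20.8, shNS -13.0). Also open and untested are separate off-targets of the 3 hairpins, a shift in the share of epithelial-like cells within the line, and the loss of Crebbp itself. With 1 library per hairpin the order of the hairpins decides nothing: hairpin 2 had the log2 ratio nearest 0 for Crebbp (-0.23, against -0.57 and -0.48 for hairpins 1 and 5) and the lowest mean for epithelial identity (-0.98, against -0.76 and -0.56), while Krt18, Spint1, St14 and Ehf were lowest with hairpin 1 (log2 ratios -1.22, -1.31, -1.37 and -1.88).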
